A study of Bos taurus with 62 samples.

How the data were processed

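RNA of cumulus cells, granulosa cells and oocytes from single follicles of heifers was sequenced in 62 libraries. Per the labels' protocols, oocyte libraries were made with a low-input kit and cumulus and granulosa libraries with another kit, so kit and cell type are confounded for oocytes. Cell types were compared by their responses to follicle type or, for cumulus against granulosa, within the shared kit, except that sets of oocyte-enriched and somatic-enriched transcripts were chosen by levels across the kits. The labels put each library in a cell type and a follicle type and number it within that group. Per the labels' protocols, 1 follicle of a type was taken per heifer, so libraries of a group came from separate animals, while Types 2 to 4 can share heifers and the labels do not tie a library to a heifer.

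Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1, trimmed with Trim Galore and quantified with kallisto 0.44.0. The genome build and transcript set were not given in the sources used here. Each of the deposited tables gives 38030 transcripts with length, effective length, estimated counts and TPM (counts per base of effective length, scaled to a common total). The deposited estimated counts, per the file headers, are not whole numbers and are not normalized. The deposited TPM values, per the file headers, are scaled by transcript length and by library total; they were not used in any test. Effective lengths were identical in all 62 tables (the length minus 199 bases for 37229 transcripts), so a correction by library-specific effective length would change nothing and was not run. None of the 38030 transcript identifiers matched the gene table used here (37063 genes of assembly ARS-UCD2.0; 0 matches). Tests were therefore made per transcript and not on sums per gene. For the same reason the gene lists, cell type markers, readout genes and mitochondrial share that had been fixed were not run. An estimated count divides reads among transcripts that share sequence, so the value of a transcript with close relatives is uncertain.

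Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Within each cell type, libraries of all 4 types entered a common quasi-likelihood fit with robust settings, TMM normalization and edgeR's expression filter by group at a minimum count of 10, which left 23100 transcripts in cumulus, 23709 in granulosa and 23744 in oocytes. Contrasts were Types 2, 3 and 4 against Type 1, Type 3 against Type 2 and Type 4 against Type 3. Cumulus and granulosa libraries were also fitted together (25957 transcripts) to test the difference between their changes from Type 1. P-values were adjusted by Benjamini-Hochberg over the transcripts of a comparison, and a transcript was called at an adjusted p under 0.05. The common biological coefficient of variation was 1.06 in cumulus, 1 in granulosa and 1.26 in oocytes. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values are counts scaled to a common library total, with TMM factors. A fold against a group with 0 counts in all libraries is a lower bound against 3 counts over that group, and covers counting error only.

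The tests, groups, the rule for named transcripts and a first set of alternatives were fixed before the data were examined. The rule took the highest and lowest log2 fold changes among called transcripts with a mean of at least 5 CPM in the higher group and every library of that group above the median of the other. Its condition of a gene symbol could not be met, and with no gene names 2 higher and 2 lower transcripts are printed, from the comparison with most calls.

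The Type 4 score of a library is the projection of its log2 CPM (prior count 2), over all tested transcripts, on the difference between the Type 4 and Type 1 means of its cell type, scaled so that Type 1 averages 0 and Type 4 averages 1. The Type 1 libraries that set the axis were kept apart from those that set the 0 point, over all ways to divide them, and a Type 4 library was left out of the axis on which it was scored. The position on the axis of another cell type uses that cell type's means for the direction and length, and the scored cell type's own Type 1 mean as 0. The identity score runs in the same way from the granulosa to the cumulus Type 1 mean. Oocyte-enriched transcripts (1451) had at least 10 CPM in oocytes and a mean level at least 32-fold above both somatic cell types, and somatic-enriched transcripts (1113) the reverse, so these sets can also hold transcripts that differ by kit. Group means of such measures were compared by two-sided exact permutation tests over all arrangements, adjusted within each family of tests. These scores were defined after the transcript counts were seen.

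The fit was tested on simulated counts with the real Type 1 means, library sizes and spread, in which 200 transcripts were changed by 2-, 4-, 8- or 16-fold. Each comparison had 1 simulated run, with 50 transcripts at each fold. With only 200 changed, the adjusted threshold is stricter than where many transcripts pass. The recovery is thus not that of the real Type 4 comparisons of cumulus and granulosa with Type 1. The changed transcripts were drawn from those with a Type 1 mean of at least 1 CPM, so recovery of less expressed ones was not measured. In cumulus Type 4 against Type 1 it recovered 10%, 28%, 40% and 70% of them, with 1 false call. In granulosa it recovered 24%, 52%, 56% and 74%, with 4 false calls, and in oocytes 4%, 26%, 42% and 48%, with 0 false calls. No pair of libraries of a group agreed within sampling noise.

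Alternatives were DESeq2 1.42.0's size factors, DESeq2's own test, other filters on low counts, a fit without robust settings, a fit of only the groups compared, an added limit of 1 on the absolute log2 fold change, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were removal of libraries that stood apart, cumulus libraries above 9 M (mega) counts only, thinning of cumulus libraries to the smallest total, removal of a trend with transcript length, and other settings of the scores. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.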

Results

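RNA was sequenced from cumulus cells, granulosa cells and oocytes of single ovulatory-size follicles of at least 10 mm, taken from heifers with a small ovarian reserve. Cumulus cells surround the oocyte and leave the follicle with it as the cumulus-oocyte complex (COC), whereas granulosa cells line the follicle wall. The heifers received a commercial pituitary FSH preparation (cpFSH) 2 times per day for 4 days, at a standard 70 IU (40 mg) per injection in 7 animals or at an excessive 210 IU (120 mg) in 6 animals, and ovaries were removed at 12 h from the final injection with no ovulatory hormone given. Type 1 follicles, the controls, came from the standard dose, held a compact COC and were estrogen-active, that is, with an estradiol to progesterone ratio in the follicular fluid of at least 1. Types 2 to 4 came from the excessive dose: Type 2 had a compact COC and was estrogen-active, Type 3 had an expanded COC and was estrogen-active, and Type 4 had an expanded COC and was estrogen-inactive. The sample labels give the Type 4 ratio as under 0.1, while the protocol text sets the limit at 1.

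The 62 libraries comprised 22 of cumulus (6, 6, 6 and 4 of Types 1 to 4), 22 of granulosa (7, 6, 5 and 4) and 18 of oocytes (5, 3, 6 and 4). Total estimated counts per library, in mega (M) counts, ranged from 3.59 to 29.4 M in cumulus (median 10.4), from 9.59 to 28.8 M in granulosa (median 18.1) and from 9.86 to 26.9 M in oocytes (median 17.3). In cumulus the depth differed between libraries of a type, with means of 14.9 ± 9.1 (SD, n = 6), 12.4 ± 6.84 (n = 6), 8.42 ± 9.01 (n = 6) and 18.2 ± 8.86 M (n = 4) for Types 1 to 4. Neither the total count, nor the number of transcripts detected, nor the share of the 10 largest transcripts differed from Type 1 past the threshold in any cell type (27 two-sided exact permutation tests, lowest adjusted p = 0.521). The smallest unadjusted p was for transcripts detected in cumulus, with 23260 ± 1195 (SD, n = 4) in Type 4 and 20769 ± 1741 (n = 6) in Type 1 (exact p = 0.0381 before adjustment). Because follicles were sorted by dose, COC form and estradiol to progesterone ratio, each comparison below is between follicle classes, and those against Type 1 are also between different animals. The files give transcript identifiers that the gene table used here does not pair with gene names, so the comparisons are of transcripts without gene names.

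The comparison of Type 2 with Type 1 asks whether the excessive dose changed the cells of follicles that still looked like control follicles. edgeR called no transcript in any of the 3 cell types. In cumulus, edgeR called 0 of 23100 transcripts, with 892 at an unadjusted p under 0.05 where 1155 are expected by chance. In granulosa it called 0 of 23709, with 729 at an unadjusted p under 0.05 against 1185 by chance. In oocytes it called 0 of 23744, with 828 against 1187. DESeq2, on the same transcripts, called 130, 133 and 468 in the 3 cell types. Other divisions of the same libraries into groups of these sizes gave it 99 to 318, 117 to 150 and 374 to 558. Chance was thus not excluded for these calls. DESeq2 counts in the later comparisons were not set beside such divisions. The design could have shown only part of the larger changes: in simulated data with these libraries' spread, the edgeR test recovered 46% of 4-fold changes in cumulus, 62% in granulosa and 18% in oocytes. Changes of that size in single transcripts were thus not excluded, and smaller ones still less so.

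**Figure D1:**
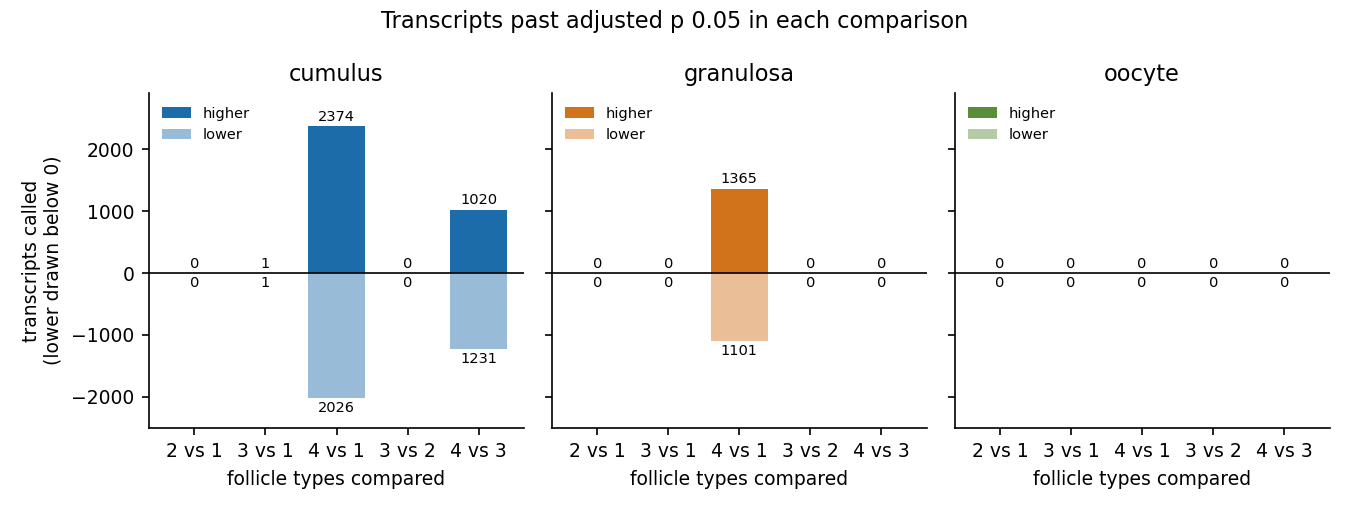
Transcripts called by edgeR's quasi-likelihood test at an adjusted p under 0.05 in each comparison of follicle types, with those higher in the first-named type above the 0 line and those lower below it, for cumulus, granulosa and oocyte libraries. Of the 15 comparisons, those with over 2 calls are cumulus Type 4 against Type 1 (2374 higher, 2026 lower), cumulus Type 4 against Type 3 (1020 and 1231) and granulosa Type 4 against Type 1 (1365 and 1101).

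Type 3 follicles, with an expanded COC and an estrogen-active fluid, differed from Type 1 in 2 of 23100 cumulus transcripts. Both were named after their values were seen, since the number of calls was so small. ENSBTAT00000010060.3 was higher, at 2.57 ± 2.58 CPM (SD, n = 6; CPM, counts scaled to a common library total) in Type 3 and 0.0134 ± 0.0329 (n = 6) in Type 1, a log2 fold change of 6.81 (SE 1.06, edgeR adjusted p = 0.031). It rests on 86 counts in Type 3 and 1 count in Type 1, and its highest library, Type 3 replicate 3, stood at 7.81 CPM. ENSBTAT00000066434.1 was lower, at 0.0373 ± 0.0913 CPM in Type 3 against 39.2 ± 20.7 in Type 1 (log2 fold change -9.48, SE 1.45, edgeR adjusted p = 0.031). A Type 1 library, replicate 1, had 0 counts of it while the other 5 lay between 35.3 and 56.1 CPM, and in Type 4 its mean was 25.2 CPM. Leaving out any 1 library of either type lost at least 1 of these 2 calls. At an unadjusted p under 0.05 there were 1929 transcripts against 1155 by chance, and DESeq2 called 313. In granulosa, edgeR called 0 of 23709 transcripts in Type 3 against Type 1, with 2017 at an unadjusted p under 0.05 against 1185 by chance, and DESeq2 called 425. In oocytes it called 0 of 23744, with 1107 against 1187 by chance, and DESeq2 called 237.

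Within the excessive dose, Type 3 against Type 2 addresses the form of the COC, since both were estrogen-active. edgeR called 0 transcripts in cumulus, granulosa and oocytes, with 1484, 1218 and 791 at an unadjusted p under 0.05, against 1155, 1185 and 1187 by chance. DESeq2 called 145, 152 and 451. Other divisions of the Type 2 and Type 3 libraries were not fitted with it, so chance was not measured for these calls. The smallest adjusted p in edgeR was 0.0596 in cumulus, 0.816 in granulosa and 0.818 in oocytes.

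Cumulus cells of Type 4 follicles, with an expanded COC and an estrogen-inactive fluid, differed widely from those of Type 1. Of 23100 transcripts, 4400 (19%) passed, of which 2374 were higher and 2026 lower, with median log2 fold changes of 2.02 and -1.72. At least 8-fold changes were called for 901 higher and 580 lower transcripts, and these counts and medians did not move when transcripts at 0 in a whole group were set at their bound. Every Type 4 library lay on one side of every Type 1 library in 4867 of all tested transcripts (21.1%), which chance gives for 0.952% with 4 against 6 libraries, and 3555 of these were among the calls. Among higher transcripts 249 had 0 counts in all 6 Type 1 libraries, and among lower ones 110 had 0 counts in all 4 Type 4 libraries. The calls reached 52.7% of the 2453 transcripts above 100 CPM and 6.48% of the 8686 between 1 and 10 CPM. Called transcripts that were higher had a median length of 2585 bases and those that were lower 2157 bases, against 2324 for all tested. A total of 7342 transcripts had an unadjusted p under 0.05 against 1155 by chance, and DESeq2 called 6016 (3057 higher, 2959 lower). Removing a per-library trend with transcript length (chosen after seeing the data) gave 1936 higher and 2457 lower, so the larger side depended on that scaling.

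By the fixed rule without its condition of a gene symbol, and limited to 2 higher and 2 lower, transcripts are named for this comparison, and their levels in granulosa stand beside them. ENSBTAT00000081398.1 stood at 198 ± 56 CPM (SD, n = 4) in Type 4 cumulus and at 0 counts in all 6 Type 1 libraries, at least 5960-fold higher against a floor of 3 counts over the Type 1 group (edgeR adjusted p = 0.013). In granulosa it was also higher, at 116 CPM in Type 4 and 1.1 in Type 1 (log2 fold change 6.78, SE 2.07, edgeR adjusted p = 0.041). ENSBTAT00000045616.4 stood at 167 ± 124 CPM in Type 4 cumulus and at 0 counts in Type 1, at least 5050-fold higher (edgeR adjusted p = 0.01), and in granulosa at 43.7 against 0.0275 CPM (log2 fold change 10.78, SE 2.75, edgeR adjusted p = 0.024). ENSBTAT00000061374.3 fell from 75.1 ± 35.3 CPM (n = 6) to 0 counts in all 4 Type 4 libraries, at least 1780-fold lower against the same floor over the Type 4 group (edgeR adjusted p = 0.0055), and 1 Type 1 library, replicate 6, was low at 6.92 CPM. In granulosa the same transcript stood at 0.921 CPM in Type 4 and 12.2 in Type 1, which did not pass (edgeR adjusted p = 0.414). ENSBTAT00000078256.1 fell from 39 ± 33.8 CPM (n = 6) to 0 counts in Type 4, at least 925-fold lower (edgeR adjusted p = 0.0061), while in granulosa it stood at 3.42 and 6.97 CPM without passing (edgeR adjusted p = 0.794). The floors cover counting error only. A transcript identifier can mark 1 of several forms of a gene, so a change of a transcript need not be a change of the gene's total.

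Granulosa cells of Type 4 follicles also differed from Type 1. Of 23709 transcripts, 2466 (10.4%) passed, with 1365 higher and 1101 lower and median log2 fold changes of 2.72 and -1.19. The higher transcripts included 639 with at least an 8-fold change, and the lower ones 105 (102 with transcripts at 0 in a whole group set at their bound, which left the medians at 2.72 and -1.19). The groups did not overlap in 1880 of all tested transcripts (7.93%), against 0.606% by chance with 4 against 7 libraries, and 1243 of these were among the calls. The median length was 2738 bases for higher, 1980 for lower and 2317 for all tested transcripts. A library of Type 4, replicate 2, lay near Type 1 on the scale described below. Without that library and Type 3 replicate 2 (removed after seeing the data) the calls were 4193, of which 2445 were higher and 1748 lower. Leaving out Type 4 replicate 1, 3 or 4 brought the calls to 1293, 1408 and 1404, and DESeq2 called 3872. With DESeq2's size factors in place of TMM, 1574 were higher and 847 lower.

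The Type 4 changes of the 2 somatic cell types ran in parallel. Across 22003 transcripts tested in both, which are not independent replicates, the log2 fold changes of Type 4 against Type 1 correlated with Pearson r = 0.513 and Spearman rho = 0.479. Calls shared between the cell types were 797 higher in both and 553 lower in both, against 133 and 97 for independent lists of these sizes, and 3 went opposite ways against 227. Of the 2364 granulosa calls among these transcripts, 57.1% were also called in cumulus in the same direction and 93.2% had the same sign there. Of the 4255 cumulus calls, 88% had the same sign in granulosa, compared with 59.3% of transcripts called in neither. Those higher in cumulus had a median log2 fold change of 0.98 in granulosa against 1.9 in cumulus, and those lower had -0.74 against -1.66. Being chosen by their cumulus values enlarges the cumulus medians, so these medians do not compare the size of the 2 responses. No library is shared between the cell types, but cumulus and granulosa libraries of one type can come from the same follicles. A test of the difference between the 2 responses (cumulus minus granulosa) called 0 of 25957 transcripts in edgeR for Types 2, 3 and 4, with 1233, 1630 and 3897 at an unadjusted p under 0.05 against 1298 by chance, and DESeq2 called 411, 434 and 1354. For Type 4 the count of 0 depended on single libraries: it became 92 without cumulus Type 3 replicate 3, granulosa Type 3 replicate 2 and granulosa Type 4 replicate 2, and, leaving out single libraries, 437 without granulosa Type 4 replicate 3, 62 without cumulus Type 1 replicate 6, 57 without granulosa Type 1 replicate 7, 5 without granulosa Type 4 replicate 2, 4 without cumulus Type 4 replicate 3 and 1 without cumulus Type 4 replicate 2 or 4.

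**Figure D2:**
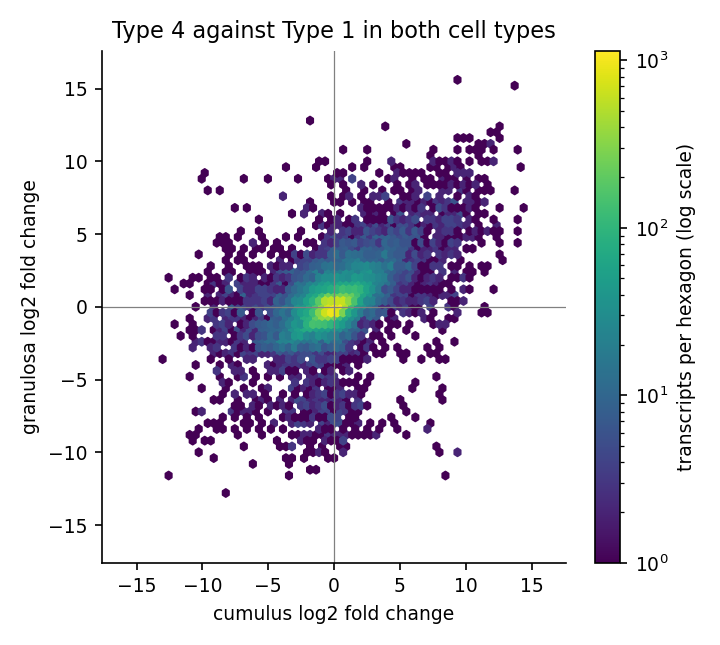
Log2 fold change of Type 4 against Type 1 in cumulus (horizontal axis) and in granulosa (vertical axis) for 22003 transcripts tested in both, as the number of transcripts per hexagon on a log colour scale. Most of the larger changes lie in the upper right and lower left, with a Pearson r of 0.513 across transcripts.

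Each library was also placed on a scale that runs from the Type 1 mean (0) to the Type 4 mean (1) of its own cell type, over all tested transcripts. In cumulus the 4 Type 4 libraries lay between 0.973 and 1.02, and the 12 libraries of Types 1 and 2 between -0.0933 and 0.2. Of the 6 Type 3 cumulus libraries, 5 lay between -0.079 and 0.0795 and 1, replicate 3, at 0.858, giving a mean of 0.147 ± 0.353 (SD, n = 6). In granulosa, Type 2 averaged 0.108 ± 0.159 (n = 6) and Type 3 0.393 ± 0.555 (n = 5), with Type 3 replicate 2 at 1.36 and replicate 3 at 0.371. The Type 3 mean was 0.00466 in cumulus without replicate 3 and 0.152 in granulosa without replicate 2, and the granulosa Type 2 mean was 0.0473 without replicate 4. The 4 Type 4 granulosa libraries lay at 1.29, 0.318, 1.21 and 1.18. Type 3 did not differ from Type 2 in cumulus (exact permutation test, two-sided, p = 0.736, adjusted p = 0.893), in granulosa (exact p = 0.255, adjusted p = 0.765) or in oocytes (exact p = 0.893, adjusted p = 0.893).

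**Figure D3:**
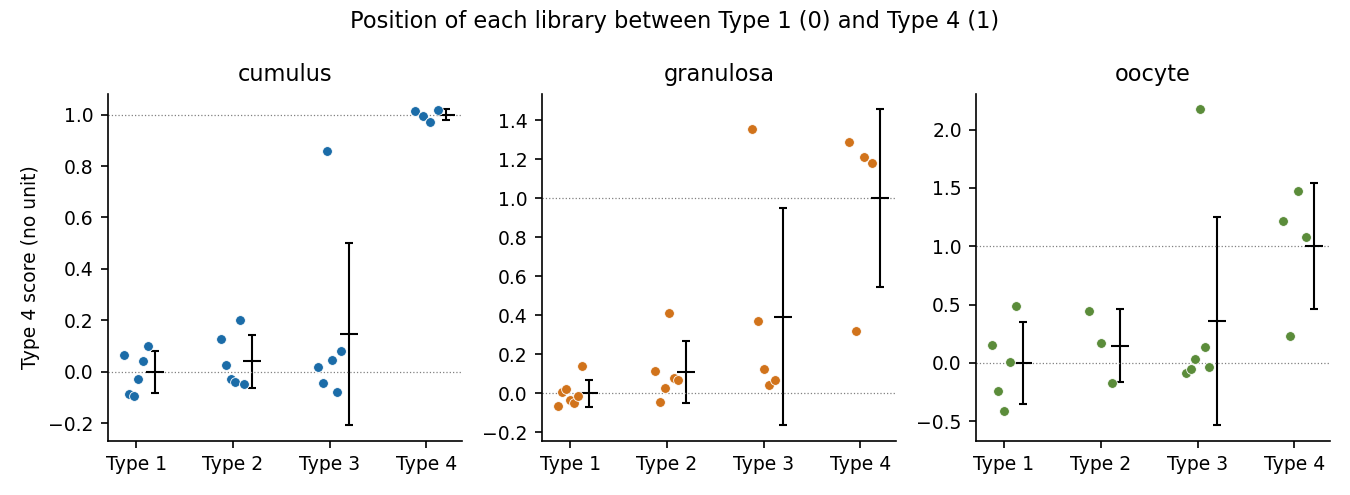
Type 4 score of each library (points) with the mean and SD of its group (dash and bars) for cumulus, granulosa and oocyte libraries, where 0 is the Type 1 mean and 1 the Type 4 mean of the same cell type. Cumulus Type 3 replicate 3 (0.858), granulosa Type 3 replicate 2 (1.36) and oocyte Type 3 replicate 4 (2.17) lie far above the other libraries of their type, and granulosa Type 4 replicate 2 (0.318) far below.

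The same question was put with the axis of the other cell type, which shares no library with the samples placed on it. The length of such an axis includes the noise of its group means, so a position is not a share of the change. For the same reason positions on the 2 axes are not on a common scale. Type 4 granulosa libraries averaged 0.439 ± 0.272 (SD, n = 4) on the cumulus axis, and Type 1 libraries averaged 0 by construction (exact permutation test, two-sided, p = 0.00303, adjusted p = 0.00909, with 4 of 4 above the highest Type 1 library). The 4 values were 0.563, 0.0612, 0.691 and 0.441. Type 3 granulosa libraries averaged 0.18 ± 0.282 (n = 5; exact p = 0.0644, adjusted p = 0.0682), again with replicate 2 apart at 0.653. Leaving out replicate 2 brought the mean to 0.0612 and the adjusted exact p to 0.227, and leaving out replicate 4 brought them to 0.235 and 0.0364. Type 2 averaged 0.0416 ± 0.0197 (n = 6; exact p = 0.0682, adjusted p = 0.0682). On the granulosa axis, Type 4 cumulus libraries averaged 0.727 ± 0.0527 (n = 4; exact p = 0.00476, adjusted p = 0.0143, with 4 of 4 above the highest Type 1 library), and cumulus Types 2 and 3 averaged 0.0453 ± 0.101 and 0.0964 ± 0.285 (n = 6 each; adjusted exact p = 0.594 and 0.656). The Type 3 mean was -0.0176 without replicate 3, and the Type 2 mean was 0.0176 without replicate 5 and 0.0774 without replicate 1.

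**Figure D4:**
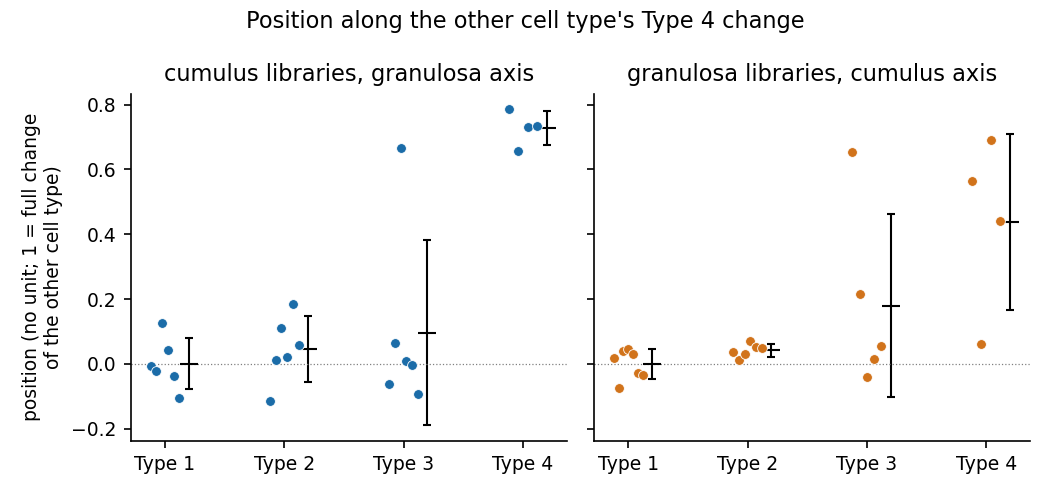
Position of each cumulus library along the granulosa change from Type 1 to Type 4 (left) and of each granulosa library along the cumulus change (right), with group means and SD. A position of 1 is the measured length of the other cell type's axis, noise included, so values are not shares of a change. The 4 Type 4 cumulus libraries lie between 0.657 and 0.785, and 3 of the 4 Type 4 granulosa libraries between 0.441 and 0.691.

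Type 4 against Type 3 addresses the loss of estrogen activity among follicles with expanded COCs. In cumulus, 2251 of 23100 transcripts passed, 1020 higher and 1231 lower in Type 4, with median log2 fold changes of 1.4 and -1.92, also with transcripts at 0 in a whole group set at their bound. The groups did not overlap in 2089 of all tested transcripts (9.04%), against 0.952% by chance, and 1000 of these were among the calls. Removing a per-library trend with transcript length (an alternative chosen after seeing the data) left 2137 calls, with 636 higher and 1501 lower. Mean depth was 8.42 M counts in Type 3 and 18.2 M in Type 4, a difference that was not tested. With all cumulus libraries thinned to the smallest total there were 2208 calls, and 1978 of the 2251 were called again in the same direction. With only libraries above 9 M counts, which leaves fewer of Type 3, 2557 were called, including 1512 of the 2251. Both alternatives were chosen after seeing the data. Leaving out Type 3 replicate 3, the library near Type 4, raised the calls to 4124, with more higher (2183) than lower (1941), while leaving out Type 4 replicate 1, 2 or 4 gave 1286, 1420 and 1276, and a fit of only these 2 groups gave 1040 (528 higher, 512 lower). DESeq2 called 3899 (1660 higher, 2239 lower). In granulosa edgeR called 0 of 23709, with a smallest adjusted p of 0.0504 and 2961 at an unadjusted p under 0.05 against 1185 by chance, and DESeq2 called 638. That 0 rested on the libraries that stood apart: the calls were 953 without Type 3 replicate 2, 463 without Type 4 replicate 2, and 2505 (1386 higher, 1119 lower) without both. Leaving out Type 4 replicate 1, 3 or 4 gave 6, 18 and 7.

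In oocytes no comparison gave a call in edgeR. For Type 4 against Type 1 it called 0 of 23744 (smallest adjusted p = 0.195), with 2857 at an unadjusted p under 0.05 against 1187 by chance, and for Type 4 against Type 3 it called 0 (smallest adjusted p = 0.278), with 2180 against 1187. DESeq2 called 889 and 549. A single library decided both counts: without oocyte Type 4 replicate 2 they were 573 and 269, and without Type 4 replicate 4 they were 2 and 2; Type 4 against Type 3 gave 1 call without Type 3 replicate 4. The Type 4 oocyte libraries scored 1.22, 0.23, 1.48 and 1.08 on the oocyte scale, and Type 3 replicate 4 scored 2.17. Type 3 replicate 4 had 16164 transcripts detected against 20929 to 21726 in the other 5 Type 3 oocyte libraries, and Type 4 averaged 19292 ± 1056 (SD, n = 4) against 21217 ± 1461 (n = 5) in Type 1 (exact permutation p = 0.103, adjusted p = 0.521). The score also followed the transcripts detected within Type 1. There replicates 2 and 3, with 22337 and 23168 detected, scored -0.243 and -0.41. Replicates 1, 4 and 5, with 19949, 20663 and 19966, scored 0.153, 0.00904 and 0.491. Replicates 2 and 3 also had the largest Type 1 shares of somatic-enriched transcripts, 0.658% and 1.2%. The oocyte score thus does not separate follicle type from these differences between libraries. The test recovered 26% of simulated 4-fold changes in the Type 4 comparison. The oocyte changes of Type 4 against Type 1 correlated with those of cumulus at r = 0.0642 across 19510 transcripts and with those of granulosa at r = 0.0536 across 19729. Of 3897 cumulus calls, 60% had the same sign in oocytes, against 51.7% of the other transcripts. Of 2153 granulosa calls it was 58.4% against 52%. These transcripts are not independent replicates. On the cumulus axis Type 4 oocytes averaged 0.0369 (exact permutation test against Type 1, two-sided, p = 0.19, adjusted p = 0.57).

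The difference between cumulus and granulosa was measured within each type as a position between granulosa Type 1 (0) and cumulus Type 1 (1). In Type 2 the cumulus libraries averaged 0.981 ± 0.374 (SD, n = 6) and the granulosa libraries -0.0114 ± 0.127 (n = 6), in Type 3 they averaged 0.889 ± 0.247 (n = 6) and 0.00943 ± 0.179 (n = 5), and in Type 4 they averaged 0.435 ± 0.116 (n = 4) and 0.158 ± 0.0362 (n = 4). The gap was 0.993 in Type 2 and 0.88 in Type 3 (exact permutation tests, two-sided, p = 0.00216 and adjusted p = 0.00756 for each) and 0.278 in Type 4, where all 4 cumulus libraries lay above the 4 granulosa libraries (exact p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0583). The difference of cumulus Type 4 minus Type 2 was -0.546 (exact p = 0.0333, adjusted p = 0.0583), and that of granulosa was 0.169 (exact p = 0.0476, adjusted p = 0.0666). Neither passed after adjustment over 7 tests. Whether the gap itself changed between types was not tested. These tests treat cumulus and granulosa libraries as unpaired, though they can come from the same follicles. Some cumulus libraries outside Type 4 also scored low, with Type 1 replicate 6 at 0.485 and Type 2 replicate 1 at 0.298. Transcripts called between cumulus and granulosa within a type were 1633 of 25957 in Type 1, 1263 in Type 2, 384 in Type 3 and 148 in Type 4, with 6 against 7, 6 against 6, 6 against 5 and 4 against 4 libraries, so the counts come from unequal numbers of libraries.

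**Figure D5:**
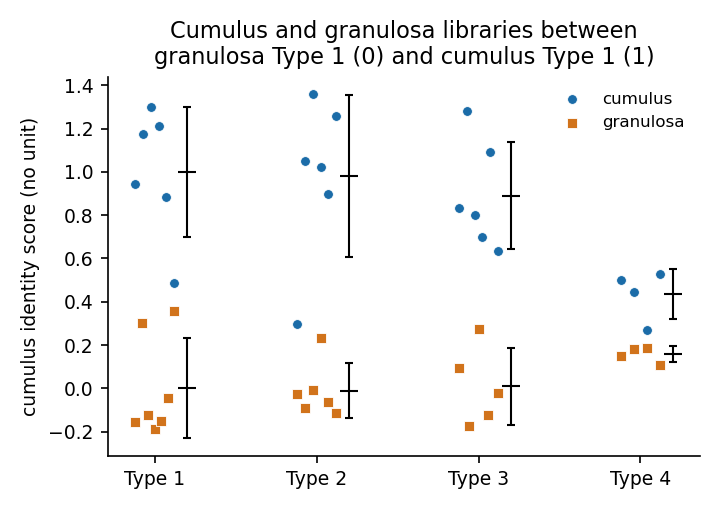
Cumulus identity score of each cumulus library (circles) and granulosa library (squares) with group means and SD, where 0 is the granulosa Type 1 mean and 1 the cumulus Type 1 mean. The cell types lie 0.993 apart in Type 2 and 0.278 apart in Type 4, and the change in this gap was not tested.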

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

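In this part, the tests of exchanged labels, of the detected transcripts of granulosa Type 3 replicate 2 and of cumulus Type 3 replicate 3 were chosen only after the result was seen. Libraries far from the rest of their group were sought in 79 groups of values, of which 20 held a library past the limit. Chance would give about 4 if the groups were normal and independent. These groups share libraries, and some hold transcripts picked for large changes, so an excess was not measured.

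In granulosa, Type 3 replicate 2 had a Type 4 score of 1.36 against 0.0406 to 0.371 in the other Type 3 libraries, and Type 4 replicate 2 had 0.318 against 1.18 to 1.29 in the other Type 4 libraries. On the cumulus axis, which uses no granulosa library, Type 3 replicate 2 lay at 0.653, inside the range of the other Type 4 granulosa libraries (0.441 to 0.691), and Type 4 replicate 2 at 0.0612, inside that of Types 1 and 2 (up to 0.0702). That upper end was Type 2 replicate 4, which itself stood apart, and the next highest library of Types 1 and 2 lay at 0.0511. The other Type 3 libraries lay between -0.0414 and 0.217. Low complexity is argued against for Type 3 replicate 2, which had 24419 transcripts detected, the most in granulosa. For Type 4 replicate 2, with 19642, it stays open: the other Type 4 libraries thinned to as few detected transcripts scored no lower than 0.427, but thinning only imitates a poor library. Granulosa Type 2 replicate 4, with 19796 detected, had a like pair of positions, a Type 4 score of 0.413 and 0.0702 on the cumulus axis. An exchange of the 2 labels is a candidate explanation, and follicles that differ within a type may give the same values, which was not tested.

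In cumulus, Type 3 replicate 3 had a Type 4 score of 0.858 against -0.079 to 0.0795 in the other Type 3 libraries, and a position on the granulosa axis of 0.666 against -0.0926 to 0.0632. Low depth is argued against: the other Type 3 cumulus libraries under 9 M counts scored at most 0.0455. An exchange with a Type 4 cumulus library is argued against too, since the lowest of these scored 0.973. Its oocyte-enriched transcripts took 0.742% of counts against 0.181% to 0.358% in the others. A single wrong label, or a follicle between Types 3 and 4, could give these values, and neither was tested.

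Other libraries stood apart in a score or a share. The Type 4 score of granulosa Type 2 replicate 4 was 0.413 (others -0.046 to 0.115), and its identity score was 0.234 (others -0.115 to -0.0078). On the cumulus axis, however, it lay at 0.0702, close to the others (0.0129 to 0.0511). Oocyte Type 3 replicate 4 scored 2.17 (others -0.0882 to 0.138) and had 16164 transcripts detected (others 20929 to 21726). Granulosa Type 1 replicate 2 had 20620 transcripts detected (others 22520 to 23799). Cumulus Type 3 replicate 6 had 26.3 M counts (others 3.59 to 9.13). The 10 largest transcripts took 13.6% in cumulus Type 1 replicate 6 (others 8.02% to 9.8%) and 8.18% in granulosa Type 1 replicate 7 (others 13.3% to 16.8%). Oocyte-enriched transcripts took 0.453% in granulosa Type 3 replicate 2 (others 0.185% to 0.197%), and somatic-enriched transcripts 0.84% in oocyte Type 3 replicate 1 (others 0.148% to 0.405%).

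Among named transcripts, ENSBTAT00000010060.3 stood at 7.81 CPM in cumulus Type 3 replicate 3 (others 0.973 to 1.94) and at 0.0805 in Type 1 replicate 5 (others 0). ENSBTAT00000066434.1 stood at 0.224 CPM in cumulus Type 3 replicate 1 (others 0) and at 0 in Type 1 replicate 1 (others 35.3 to 56.1). ENSBTAT00000061374.3 stood at 6.92 CPM in cumulus Type 1 replicate 6 (others 74.8 to 101).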

How the results depend on the processing

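Chosen only after seeing the data were the removal of libraries that stood apart, the limit of 9 M counts, thinning, removal of a trend with transcript length, and the settings of the scores other than those of the tests. Of 399 counts of calls under an alternative, 314 stayed within 1.5 times the reported count and 85 did not. Many of the 314 are comparisons without calls that stayed without calls, so this share does not measure the stability of the calls. Of 127 values of named transcripts, 96 kept their side of the threshold and 31 lost the call, and none changed direction. Cumulus Type 4 against Type 1 (4400 calls) stayed within 1.5 times under every alternative run. Cumulus libraries went down to 3.59 M counts, and with all of them thinned to that total Type 4 against Type 1 gave 4238 calls. The alternatives that need gene names (the set test, the pseudocount of marker lists) and the offset for effective length, identical in all libraries, were not run. The cause was not tested for the changes below, except that fewer libraries or transcripts entered where the setting says so.

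In cumulus Type 3 against Type 1 the 2 calls became 0 without a filter on low counts, 1 with a mean of at least 50 counts, 0 in a fit of only these groups, 0 with libraries above 9 M counts, 1 after thinning and 0 without Type 3 replicate 3; thinning gave 1 call in Type 3 against Type 2. Cumulus Type 4 against Type 3 (2251) gave 1040 in a fit of only these groups and 4124 without Type 3 replicate 3, and higher calls outnumbered lower ones in both and, by 1283 to 1274, with libraries above 9 M counts. Granulosa Type 4 against Type 3 (0) gave 1 with DESeq2's size factors, 1 with a mean of at least 50 counts, 1 without robust settings and 1 with the length trend removed. Without granulosa Type 3 replicate 2 and Type 4 replicate 2 it gave 2505, and Type 4 against Type 1 gave 4193. Oocyte Type 2 against Type 1 gave 1 in a fit of only these groups. Without oocyte Type 3 replicate 4 and Type 4 replicate 3, Type 4 gave 2 against Type 1 and 2 against Type 3. The difference between cumulus and granulosa in Type 4 gave 92 without the 3 somatic libraries that stood apart.

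DESeq2's test called more in each comparison. In cumulus it called 130, 313 and 6016 for Types 2, 3 and 4 against 1. For cumulus Type 3 against 2 and Type 4 against 3 it called 145 and 3899. In the same order it called 133, 425, 3872, 152 and 638 in granulosa and 468, 237, 889, 451 and 549 in oocytes. For the differences between cumulus and granulosa it called 411, 434 and 1354 in Types 2, 3 and 4.

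Leaving out each library in turn gave 0 to 1 calls in cumulus Type 2 against 1, 0 to 1 in Type 3 against 1, 3212 to 4080 in Type 4 against 1, 0 to 1 in Type 3 against 2 and 1276 to 4124 in Type 4 against 3. In granulosa Type 4 it gave 1293 to 3649 against Type 1 and 0 to 953 against Type 3, and 0 in the other comparisons. In oocytes it gave 0 to 1 for Type 2 against 1, 0 to 1 for Type 3 against 1, 0 to 573 for Type 4 against 1, 0 to 3 for Type 3 against 2 and 0 to 269 for Type 4 against 3, and for the Type 4 difference between cumulus and granulosa 0 to 437. The position of Type 4 cumulus on the granulosa axis (0.727) was 0.868 with a mean of at least 50 counts and 0.644 with a prior count of 0.5, and the adjusted exact p of granulosa Type 3 on the cumulus axis was 0.0364 without Type 3 replicate 4 and 0.0636 to 0.227 without any other Type 3 library.

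The replicate numbers did not clearly pair the libraries within a cell type. In no comparison did every same-numbered pair correlate above 0.1, and the lowest correlation was -0.412, in granulosa Type 4 against Type 3. In no comparison did every library correlate best with its own number. In Type 3 against Type 2, however, 3 of 5 did in granulosa and 2 of 3 in oocytes. Comparisons with Type 1 are between different animals, so no pairing by heifer could show there. Whether numbers mark heifers among Types 2 to 4 stays open. Same-numbered libraries of different cell types were not compared. With the number as a replicate block, the calls were 0 in cumulus Type 3 against 1, 1412 (743 higher, 669 lower) in cumulus Type 4 against 3, 3 in granulosa Type 4 against 1 and 1 in oocyte Type 4 against 1, and cumulus Type 4 against 1 gave 3187.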

Other observations

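In this part, the tests of depth, transcript length and dilution, the DESeq2 fits of other splits and the counts of splits by unadjusted p were chosen only after the result was seen, whereas the edgeR calls in other splits were planned.

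Transcripts enriched in oocytes, a set chosen across the library kits, took a larger mean share of counts in Type 4 somatic cells. In cumulus the share was 0.476% ± 0.0661 (SD, n = 4) in Type 4 and 0.285% ± 0.109 (n = 6) in Type 1 (exact permutation p = 0.0238, adjusted p = 0.107 over 9 tests). In granulosa it was 0.397% ± 0.131 (n = 4) and 0.196% ± 0.0309 (n = 7; exact p = 0.00909, adjusted p = 0.0818), so neither passed after adjustment. Somatic-enriched transcripts took 15.6% ± 1.53 (n = 4) of counts in Type 4 cumulus and 20% ± 1.05 (n = 6) in Type 1, and 17.3% ± 4.14 (n = 4) and 22.5% ± 2.9 (n = 7) in granulosa, which were not tested. Both sets were chosen by mean levels over all libraries of a cell type, most of them of Types 1 to 3. That choice can by itself shift the shares in Type 4 somatic cells. In oocytes somatic-enriched transcripts took 0.239% ± 0.0428 (n = 4) in Type 4 and 0.47% ± 0.463 (n = 5) in Type 1 (exact permutation p = 0.437, adjusted p = 0.744).

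For the Type 4 calls against Type 1, 3 technical explanations were weighed. After all cumulus libraries were thinned to the smallest total, 86.8% of the cumulus calls were called again in the same direction, which argues against depth as the whole cause. After a trend with transcript length was removed, 86.6% of the cumulus and 84.7% of the granulosa calls were. Dilution by RNA of other cells stays open for the lower calls: 14.1% of tested transcripts in cumulus and 11.7% in granulosa fell by as much as the median lower call, but normalization centres the median of all transcripts (log2 fold changes of -0.06 and 0.07), so a fall shared by most transcripts would not show. The mean share of somatic-enriched transcripts was lower in Type 4, but the choice of that set mostly by Types 1 to 3 can give this too, so it does not decide the question. RNA of other cells may also underlie part of the higher calls, which were not tested without gene names, and the change of follicle class itself stays open as the biological explanation.

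Other splits of the same libraries into groups of the same sizes were fitted, up to 100 per comparison. For cumulus Type 4 against Type 1, 1 of 100 splits (of 210 possible), the real one, gave as many as 4400 calls. The highest other gave 3, which argues against a chance division of the libraries. The splits do not address that Type 1 libraries came from other heifers. For granulosa Type 4 against Type 1 (2466) it was also 1 of 100, with 1707 in the highest other, a split that exchanged Type 1 replicate 7 and Type 4 replicate 2. For cumulus Type 4 against Type 3 (2251) it was 1 of 100, with 1718 in the highest other, which exchanged Type 4 replicate 1 and Type 3 replicate 3. For the 2 calls of cumulus Type 3 against Type 1 it was 1 of 100, with 1 in the highest other. But 9 of 100 splits gave at least the real 1929 transcripts at an unadjusted p under 0.05 (highest other 2768), so these 2 calls stay uncertain. The fit of simulated counts for this comparison made 5 false calls beside 200 changed transcripts, which gives no rate for so few calls.

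Where edgeR gave 0 calls, the number of splits with as many is fixed at all of them (100 of 100, 56 of 56 in oocyte Type 2 against 1 and 84 of 84 in oocyte Type 3 against 2) and says nothing about chance; the counts at an unadjusted p under 0.05 and by DESeq2 stand beside each comparison above. The highest other split gave 1 in cumulus Type 2 against 1 and Type 3 against 2, 1 in granulosa Types 2 and 3 against 1 and Type 3 against 2, and 1, 1, 3, 2 and 4 in oocyte Types 2, 3 and 4 against 1, Type 3 against 2 and Type 4 against 3. In granulosa Type 4 against Type 3 it gave 1611, in a split that put Type 3 replicate 2 with the Type 4 libraries, and for the differences between cumulus and granulosa 3, 1296 and 713 in Types 2, 3 and 4. So many calls where the real split has 0 point to a structure of the samples, and what it is was not tested for the differences.

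For the comparisons with 0 calls in edgeR, the splits were also counted by transcripts at an unadjusted p under 0.05. As many as in the real split were found in 2 of 100 splits in oocyte Type 4 against 1 (2857 transcripts; DESeq2 889 calls) and in 4 of 100 in granulosa Type 3 against 1 (2017; DESeq2 425). They were found in 63 and 39 of 100 in cumulus Type 2 against 1 and Type 3 against 2, and in 21, 72 and 18 of 100 in granulosa Type 2 against 1, Type 3 against 2 and Type 4 against 3. In oocytes it was 33 of 56 for Type 2 against 1, 25 of 100 for Type 3 against 1, 74 of 84 for Type 3 against 2 and 14 of 100 for Type 4 against 3. For the differences between cumulus and granulosa it was 96, 63 and 9 of 100 in Types 2, 3 and 4. These 14 counts were not adjusted for their number.

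DESeq2's calls for Type 2 against Type 1, where edgeR called 0 (892, 729 and 828 at an unadjusted p under 0.05), were also set beside other splits, 20 per cell type with the real one included. In cumulus 12 of 20 splits gave at least the real 130 calls (others 99 to 318, median 133), in granulosa 8 gave at least 133 (others 117 to 150, median 130) and in oocytes 4 gave at least 468 (others 374 to 558, median 418), so chance was not excluded for these calls.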
